A study of Mus musculus with 2 samples.

How the data were processed

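Single-cell RNA-seq was made from 2 libraries of mouse mammary cells, 1 per group, so that no test between groups was possible. The library called Ctrl came from mice with both alleles of the miR-200c/141 locus flanked by loxP sites, and the library called cKO from mice that also carried a tamoxifen-inducible Cre driven by the promoter of keratin 8, a luminal keratin (K8-CreERT2). Per the labels, C57BL/6 mice received tamoxifen at 8 to 10 weeks of age, glands were taken 4 weeks later and mammary cells were enriched by FACS. The labels also give an age of 8 weeks, and they do not say how many mice were pooled in a library. Libraries were made with the 10x Chromium 3′ v2 chemistry, per the labels' protocols.

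The deposited values were counts, whole numbers of unique molecular identifiers (UMIs) per gene and cell barcode, with no normalization. Per the submitters' processing notes, Cell Ranger 2 and mm10 were used, while the software version recorded in the file headers is 3.0.0, so the exact version was left open. The files held 31053 genes, of which 31011 (99.86%) were found by identifier in GENCODE M21, an annotation of the same build. They held 4237 barcodes with 95520633 UMIs for Ctrl and 6257 barcodes with 103668011 UMIs for cKO. The lowest total per barcode was 502 and 500 UMIs.

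Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were used, which left 3416 Ctrl and 5493 cKO cells. Scrublet, run per library with an expected rate of 0.8% per 1000 cells, called 9 Ctrl and 58 cKO cells as doublets, 0.26% and 1.06%. These are low rates for such libraries, so undetected pairs of cells remained. Removing the calls left 3407 Ctrl cells with a median of 19843 UMIs and 5435 cKO cells with a median of 13917. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours entered Leiden clustering at resolution 0.5, without batch integration.

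No cell annotation was used from elsewhere, so cell names were rebuilt from 15 marker lists fixed before the data were examined. The rule that turns marker scores into names was written after the first clustering had been seen. It asked for a mean marker score of at least 0.4 and at least 3 detected markers, and it kept luminal clusters with a score of at least 0.2 for both luminal kinds apart as a class with both marker sets. Luminal-like cells are the hormone-sensing-like and luminal-progenitor-like cells together, and epithelial-like cells add the basal-like ones. The endothelial-like cells are given by cluster, a choice made after the data were seen because cluster 8 also scored high for myeloid markers.

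Counts were summed per class and library and scaled to a total of 1000000 UMIs (CPM). Levels carry exact Poisson intervals, shares exact Clopper-Pearson intervals and ratios exact conditional binomial intervals, all at 95%. These intervals cover counting error only and say nothing of the spread between mice. For ranks and medians, a sum of 0 was set to a floor of 3 counts in that library. A single fold against a sum of 0 is given as the lower bound of its 95% interval. To compare shares of cells with a UMI, each cell was thinned to 1000 UMIs and shallower cells were left out. For Ccnd1 the share expected over all thinnings was added after the data were seen, with 2000 bootstrap draws of cells. Where no cell held a UMI, the limit that 3 counts of the total allow is given. Basal-like and endothelial-like cells gave the background for Esr1.

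For 34 gene lists, the 15 marker lists among them, the members with at least 20 UMIs were counted as at least 1.5-fold higher or lower in cKO. The median log2 ratio of each list was placed among 10000 random lists of the same size matched on mean expression, as a description of these libraries. Named genes followed a rule fixed before the data were examined. In each of the 3 epithelial classes it takes the 10 highest and 10 lowest CPM ratios among genes with at least 100 UMIs in the higher library and found in at least 5% of its cells, without clone-named models and pseudogenes. To these it adds Esr1, Pgr, Ccnd1, Krt8, Krt18, Zeb1 and Zeb2, and up to 4 members of each list, those farthest from 0 with at least 50 UMIs. Genes named outside this rule were chosen after their values were seen, which is said beside them. Classes with fewer than 100 cells in a library were not compared. The endothelial-like clusters 8 and 9 reach 110 Ctrl cells together but 55 each, so their separate values fall outside this minimum.

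Seed sites were searched in the longest annotated 3′ untranslated region of each gene, in GRCm38 with GENCODE M21. A site was a match to bases 2 to 8 of miR-200c-3p (CAGTATT) or miR-141-3p (CAGTGTT), whose sequences were read from the genome at the annotated hairpins. Of 20986 genes with a 3′ untranslated region, 2788 held a miR-200c site and 3600 a miR-141 site. Genes with at least 50 UMIs in luminal-like cells were compared.

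The calculations were tested on simulated data: counts of hormone-sensing-like cells were drawn for 12268 genes, of which 50 each had their cKO share multiplied by 1.5, 2, 4 or 0.25. Median log2 ratios of 0.37, 0.76, 1.77 and -2.23 were recovered where 0.38, 0.80, 1.80 and -2.20 had been put in after rescaling. The intervals held the true value for 86.0%, 92.0%, 98.0% and 96.0% of these genes and for 95.8% of the unaltered ones. All 28 lists raised 2-fold lay above the 97.5th percentile, and a raise of 0.2 in genes with a miR-141 site was recovered as 0.20.

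Alternatives covered the cell filter, doublet removal, clustering resolution, clustering each library alone, scaling (trimmed mean of M values from edgeR, CPM without mitochondrial, ribosomal and hemoglobin genes, and means of cells), thinning depth, count minimums and the seed definition. Alternatives chosen after the data had been seen were clustering without the 1955 genes that differed 2-fold between the libraries within a class, leaving out cluster 11, leaving out the 3 cells with the most UMIs of each milk gene, and other ways to count the clusters with both marker sets. Versions were Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.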

Results

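Messenger RNA was counted in single mammary cells of adult mice in 1 control library (Ctrl) and 1 library from mice given an inducible deletion of the miR-200c/141 locus (cKO). The Ctrl library held 3407 cells with 93561131 UMIs after filtering, and the cKO library 5435 cells with 101171939 UMIs. With 1 library per group there are no replicates, so every interval below is a counting interval and every difference may belong to the mice, the dissociation or the sort as much as to the genotype. The comparison addresses, as the series title frames it, how loss of these microRNAs affects the expression pattern of the estrogen receptor gene Esr1 and the level of Ccnd1, which encodes the cell cycle protein cyclin D1.

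Hormone-sensing-like cells, the luminal kind that carries the receptors for estrogen, progesterone and prolactin, made up 42.7% of 1203 luminal-like cells in Ctrl (95% Clopper-Pearson interval 39.9 to 45.6) and 57.0% of 2389 in cKO (55.0 to 59.0). Basal-like cells, the contractile outer layer with Krt5 and Krt14, made up 47.4% of epithelial-like cells in Ctrl (45.3 to 49.4) and 29.2% in cKO (27.6 to 30.7). Of all kept cells, luminal-progenitor-like cells, the milk-lineage luminal kind with Aldh1a3 and Csn3, were 20.2% in Ctrl and 18.9% in cKO. Luminal clusters with the markers of both kinds held 28.2% (26.7 to 29.7) and 25.998% (24.8 to 27.2), and are left out of the luminal-like cells. Cells were enriched by FACS, and these shares hold for what the gate passed.

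The libraries separated within classes. Hormone-sensing-like cells were cluster 7 in Ctrl (512 cells) and clusters 11 and 12 in cKO (350 and 1011 cells), and basal-like cells were mostly cluster 0 in Ctrl (963 cells) and cluster 6 in cKO (895 cells), so that such clusters can stand for a library rather than a cell type. Clustered at resolution 1.0 without the genes that differed 2-fold between the libraries, hormone-sensing-like cells were 42.2% of luminal-like cells in Ctrl and 54.3% in cKO, and basal-like cells 46.7% and 30.03% of epithelial-like cells. At resolution 0.5 without these genes, where only 17 Ctrl cells were named hormone-sensing-like, that share differed by 52.1 points. Without cluster 11 the hormone-sensing-like share in cKO was 49.6%, and with each cell of the clusters with both marker sets counted as 1 of each kind the shares were 47.2% and 53.2%.

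**Figure D1:**
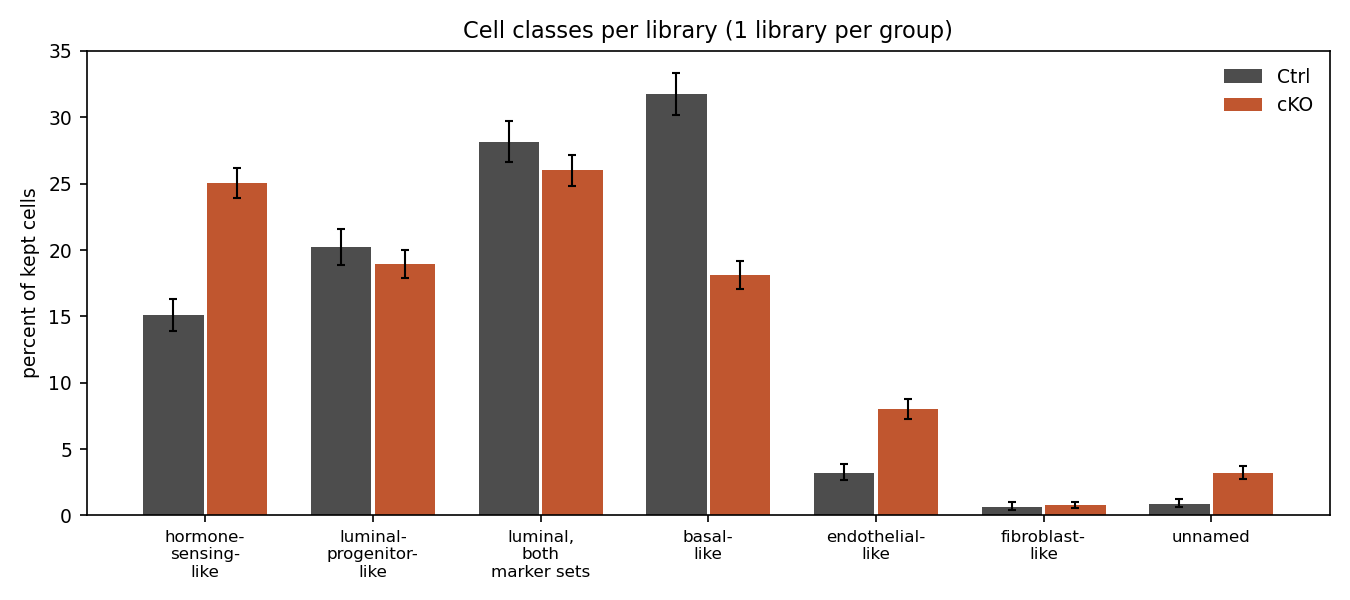
Bars show the percent of kept cells in each rebuilt class for the Ctrl and cKO libraries, with 95% Clopper-Pearson intervals. Hormone-sensing-like cells were 15.1% and 25.04%, and basal-like cells 31.8% and 18.1%.

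The deletion itself could not be checked, because the microRNAs are not among the counted genes. Mir200c lies on chromosome 6 from 124718322 to 124718390 and Mir141 from 124717914 to 124717985, both on the minus strand of GRCm38. Of 6 preset genes near this locus, 0 were at least 1.5-fold higher and 2 at least 1.5-fold lower in hormone-sensing-like cells of cKO. Lpcat3, which encodes a phospholipid-remodelling enzyme, stood at 112 CPM in Ctrl and 45.2 CPM in cKO there, and Ptpn6, which encodes the phosphatase SHP-1, at 13.7 and 6.91 CPM. The median log2 ratio of these neighbours was -0.32 in hormone-sensing-like, -0.13 in luminal-progenitor-like and -0.18 in basal-like cells. These medians lay at percentiles 12.3, 42.7 and 7.7 of random matched lists, so they do not show a change at the locus.

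Ccnd1 (ENSMUSG00000070348, chromosome 7, 144929931 to 144939925, minus strand) was higher in luminal-progenitor-like cells of cKO. In luminal-progenitor-like cells it stood at 81.1 CPM in Ctrl (76.8 to 85.6) and 157.7 CPM in cKO (151.4 to 164.3), a ratio of 1.94 (1.82 to 2.08). In hormone-sensing-like cells the levels were 94.7 and 101.9 CPM, a log2 ratio of 0.11 (0.00 to 0.21), and in basal-like cells, where Krt8, whose promoter drives the Cre, stood at 716 and 625 CPM, it was 32.0 and 31.4 CPM, a log2 ratio of -0.02 (-0.26 to 0.21). In the luminal clusters with both marker sets it was also higher in cKO, at 87.3 and 139.1 CPM, a log2 ratio of 0.67 (0.61 to 0.73). After thinning to 1000 UMIs, 7.69% of luminal-progenitor-like cells in Ctrl and 13.0% in cKO held a Ccnd1 UMI, against 6.82% and 9.90% of hormone-sensing-like, 8.24% and 12.9% of both-marker and 1.95% and 3.36% of basal-like cells. Endothelial-like cells give no background for Ccnd1, since it stood at 553 and 674 CPM in cluster 8 and at 79.7 and 75.8 CPM in cluster 9, and 19.1% and 34.3% of them held a UMI. At 2000 UMIs the luminal-progenitor-like shares were 13.9% and 20.9% and the basal-like ones 5.22% and 4.85%. Averaged over all possible thinnings to 1000 UMIs, a calculation added after these draws were seen, the shares were 7.09% and 12.3% in luminal-progenitor-like, 8.04% and 8.89% in hormone-sensing-like and 2.70% and 2.62% in basal-like cells. At 2000 UMIs these averages were 14.9% and 16.5% in hormone-sensing-like and 14.9% and 22.0% in both-marker cells. Without thinning the luminal-progenitor-like shares were 55.4% and 57.9%, at median depths of 19808 and 11687 UMIs, and 0 and 1 cells were too shallow to be thinned.

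Scaling by trimmed means moved the median log2 ratio of all genes with at least 100 UMIs in luminal-progenitor-like cells by 0.11, from -0.13 to -0.01, and in luminal-like cells by 0.11. With that shift, Ccnd1 in luminal-progenitor-like cells moved from a log2 ratio of 0.96 with CPM to 1.07 with trimmed means. In hormone-sensing-like cells the Ccnd1 ratio turned to -0.02 without cluster 11, so no direction is given for it there.

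The longest annotated 3′ untranslated region of Ccnd1 holds 2676 bases, with 0 matches to the miR-200c site and 1 to the miR-141 site, at base 950. Zeb1 and Zeb2, which encode repressors of epithelial genes and are textbook targets of this microRNA family, each hold 5 miR-200c and 4 miR-141 sites. Zeb1 stood at 3.38 CPM in Ctrl and 2.06 CPM in cKO in luminal-progenitor-like cells, a log2 ratio of -0.71 (-1.41 to -0.05), and at 0.692 and 0.686 CPM in hormone-sensing-like cells. Zeb2 had 4 and 6 UMIs in luminal-progenitor-like cells and 0 and 4 in hormone-sensing-like cells, too few to show a difference at this depth. Of 22 measured genes reported as targets of the family, Ccnd1 among them, 2 were at least 1.5-fold higher and 3 at least 1.5-fold lower in luminal-like cells of cKO, with a median log2 ratio of -0.14 at percentile 39.8 of random matched lists.

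Genes with a miR-200c site had a median log2 ratio of -0.15 in luminal-like cells (1788 genes) and genes with a miR-141 site one of -0.14 (2412 genes), against -0.10 for 8008 genes with neither. These differences of -0.04 and -0.04 lay at percentiles 0.495 and 0.94 of random lists matched on expression. Against lists matched also on the length of the 3′ untranslated region, the differences were -0.000614 and 0.00502, at percentiles 48.8 and 66.9. Without matching on length, the genes with a site lay below those without by -0.09 and -0.07 in luminal-progenitor-like cells. In hormone-sensing-like cells they lay above by 0.03 and 0.03. Against lists matched on expression and length, the luminal-progenitor-like differences were -0.012 and 0.00092, at percentiles 9.5 and 55.6. The hormone-sensing-like ones were 0.017 and 0.015, at percentiles 86.0 and 89.8, so opposite shifts in both luminal kinds are not shown. A general upward shift of genes with a site was not detectable in the luminal-like cells. A raise of 0.2 put into simulated hormone-sensing-like sums was recovered, but those sums held no other difference between the libraries. A smaller shift in the luminal-like cells is therefore not excluded.

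Esr1 (ENSMUSG00000019768, chromosome 10, 4611593 to 5005614, plus strand) stood at about the same level in hormone-sensing-like cells of both libraries. It had 40.6 CPM in Ctrl (37.0 to 44.4) and 40.5 CPM in cKO (37.8 to 43.2), a log2 ratio of -0.00 (-0.17 to 0.16). In luminal-progenitor-like cells it stood at 2.83 and 2.20 CPM, a log2 ratio of -0.36 (-1.06 to 0.32), and in basal-like cells at 2.13 and 3.32 CPM, a log2 ratio of 0.64 (-0.19 to 1.47). Pgr, the progesterone receptor gene and an estrogen target, stood at 90.6 and 81.4 CPM in hormone-sensing-like cells and at 6.76 and 4.12 CPM in luminal-progenitor-like cells, with log2 ratios of -0.15 (-0.27 to -0.04) and -0.71 (-1.19 to -0.25). The Pgr ratio in hormone-sensing-like cells was 0.03 without cluster 11.

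The share of luminal-like cells with an Esr1 UMI after thinning was 2.25% in Ctrl (27 of 1202 cells, 1.49 to 3.25) and 3.07% in cKO (73 of 2381 cells, 2.41 to 3.84), with overlapping intervals and 1 and 8 cells left out. Within hormone-sensing-like cells it was 4.29% (2.71 to 6.42) and 5.10% (3.99 to 6.41), and within luminal-progenitor-like cells 0.726% and 0.389%. The background was 0.0930% and 0.102% in basal-like cells, 1 cell in each library, and 0 of 110 cells in Ctrl and 0.231% in cKO in endothelial-like cells, where the count of 0 allows a share of up to 2.73%. Without thinning 25.8% and 24.6% of luminal-like cells held an Esr1 UMI, at median depths of 20215.0 and 12666 UMIs, against 2.495% and 2.54% of basal-like cells at 10226.5 and 7263 UMIs. In both-marker cells, left out of these shares, 1.67% and 2.19% held an Esr1 UMI after thinning. No spread of Esr1 to luminal-progenitor-like cells of cKO was seen. These values cannot exclude it, because Esr1 is a hormone-sensing marker and clusters with both marker sets were named apart. Cluster 11 of cKO, named hormone-sensing-like, held Esr1 UMIs in 58.3% and Aldh1a3 UMIs in 49.4% of cells, without thinning.

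**Figure D2:**
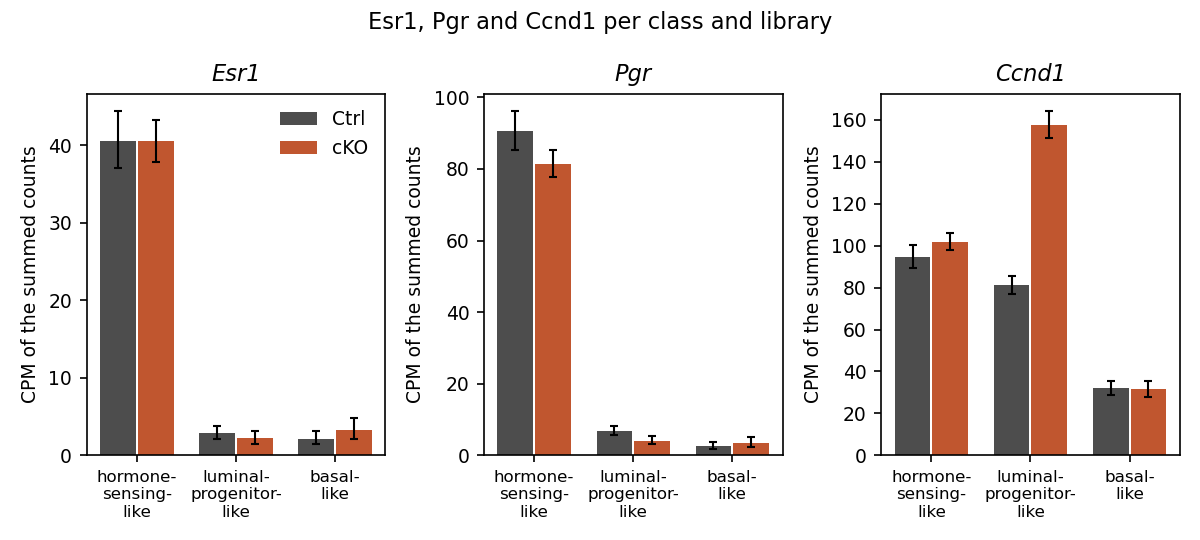
Bars show CPM of the summed counts of Esr1, Pgr and Ccnd1 in 3 epithelial classes of the Ctrl and cKO libraries, with 95% Poisson intervals. Esr1 in hormone-sensing-like cells was 40.6 and 40.5 CPM, and Ccnd1 in luminal-progenitor-like cells 81.1 and 157.7 CPM.

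Estrogen receptor targets went both ways in hormone-sensing-like cells. Of 17 measured targets, 4 were at least 1.5-fold higher and 4 at least 1.5-fold lower in cKO, with a median log2 ratio of -0.07 at percentile 32.5. Tnfsf11, which encodes the paracrine signal RANKL, had 142 UMIs in Ctrl and 3 in cKO, a level 89.6-fold lower in cKO (30.03 to 439), and the lysosomal protease gene Ctsd stood at 1259.6 and 308 CPM. Cxcl12, which encodes a chemokine, was higher in cKO, at 1.30 and 32.9 CPM, and so was Greb1, an estrogen-induced gene, at 16.4 and 59.3 CPM. Targets chosen after their values were seen were Cited1, at 2396 and 685 CPM, Wnt4, at 402 and 154 CPM, and the growth factor gene Areg, at 2716 and 4059 CPM. Without cluster 11 the median of the list was -0.36, at percentile 1.42, with 3 of 16 targets higher and 6 lower. A separate list of the estrogen receptor and its partners had 3 of 11 members higher and 3 lower. Its median was -0.44 at percentile 1.8, or -0.37 at percentile 5.5 without cluster 11. Clustered at resolution 1.0 without the genes that differed 2-fold between the libraries, it was -0.18 at percentile 27.9.

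Interferon-stimulated genes were higher in both luminal classes of cKO. In hormone-sensing-like cells 15 of 17 were at least 1.5-fold higher and 0 lower, with a median log2 ratio of 1.54 at percentile 100 of random lists, and 11 of 15 were higher without cluster 11, with a median of 1.12. Markers of other cell types were higher there as well, with medians of 2.19 for myeloid, 1.95 for T and NK cell and 1.35 for endothelial markers, or 0.58 for myeloid and 0.97 for endothelial markers without cluster 11. Ifit1, an antiviral RNA-binding protein gene, stood at 0.865 CPM in Ctrl and 10.5 CPM in cKO, or 3.32 CPM without cluster 11, Irf7, an interferon transcription factor gene, at 3.29 and 13.1 CPM, and Rsad2, the viperin gene, at 4.93 and 19.4 CPM. In luminal-progenitor-like cells 11 of 18 were higher and 1 lower, with a median of 0.73, among them Isg15, a ubiquitin-like modifier gene, at 24.2 and 65.6 CPM, while 3 of 5 myeloid markers were higher there, with a median of 1.04. In basal-like cells 5 of 15 were higher and 2 lower, with a median of 0.02 at percentile 46.9.

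Further lists separated the hormone-sensing-like cells of the 2 libraries, some of them largely through cluster 11. Lipid metabolism genes did not rest on it, with a median log2 ratio of 0.43, or 0.47 without it. Antigen presentation genes stood at 0.50, or 0.33 without it. Clustered without library-specific genes at resolution 1.0, lipid metabolism and antigen presentation genes stood at 0.60 and 0.53. Basal markers had a median log2 ratio of 1.91, luminal progenitor markers of 1.80 and milk and secretory genes of 1.79, which were 0.43, -0.29 and 0.20 without cluster 11. Clustered without library-specific genes at resolution 1.0, basal markers stood at -1.38 and luminal progenitor markers at -0.59, so these 2 lists have no stable direction. Milk and secretory genes stood at 0.48 there and so stayed above 0 in each of these settings, but without cluster 11 only at percentile 88.3 of random lists. Cytokine and acute-phase genes had 10 of 16 members higher and 4 lower, but 5 of 15 higher and 5 lower without cluster 11, where the median was -0.05 in place of 1.05. The iron-binding protein gene Ltf stood at 2.16 CPM in Ctrl and 75.4 CPM in cKO, or 5.17 CPM without cluster 11. Hif1a, which encodes the oxygen-regulated transcription factor subunit, stood at 158 and 567 CPM and its target Vegfa at 51.9 and 124 CPM, within a list of hypoxia and glycolysis genes with 4 of 13 higher and 0 lower, or 2 of 13 higher without cluster 11. Of 15 mitotic genes 3 were higher and 7 lower, with a median of -0.58 at percentile 1.58, or -0.56 without cluster 11. Dividing cells could fall in a cluster outside this class, so this value does not compare cell division between the libraries.

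Among single genes of hormone-sensing-like cells, Foxj1, the master transcription factor gene of motile cilia, had 2 UMIs in Ctrl and 302 in cKO, a ratio of 79.8 (21.9 to 662), and the dynein light chain gene Dynlrb2 had 3 and 450 UMIs, a ratio of 79.3 (27 to 386). Il33, which encodes an alarmin cytokine, stood at 1.56 and 128 CPM. The log2 ratios of Foxj1 and Il33, 6.32 and 6.36, were 4.13 and 4.46 without cluster 11, and that of Dynlrb2, 6.31, was 3.65. Apart from the leading genes of cluster 7, among them Calca with the lowest ratio, the lowest ratios were those of Hsd11b2, which encodes the enzyme that inactivates glucocorticoids, with 379 and 2 UMIs and a level 359-fold lower in cKO (98.6 to 2972), and of Sftpd, a collectin gene, at 28.1 and 0.183 CPM. Xlr4a, Klk1b8 and Fmo1 had 0 UMIs in cKO, with lower bounds of 84.7-fold, 76.0-fold and 57.0-fold for how much lower they stood. Calca, Wfdc12, Cbr2 and Pifo, also named by the rule, are among the genes that set clusters 7 and 11 apart and are not given as differences here.

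**Figure D3:**
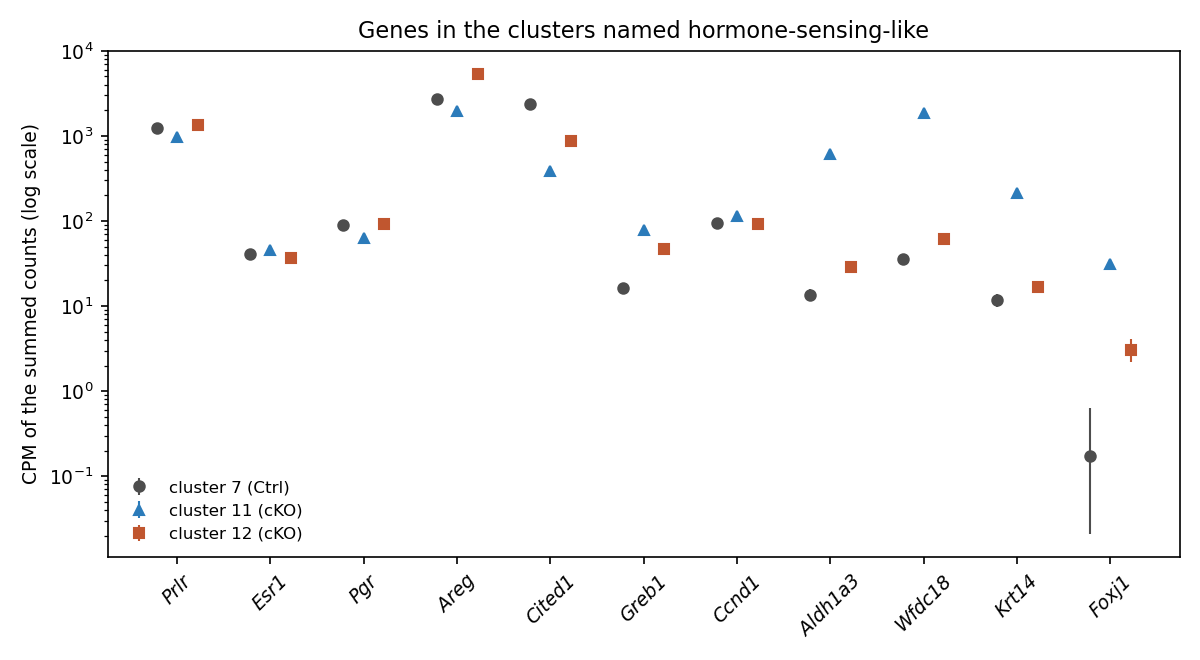
Points show CPM on a log scale, with 95% Poisson intervals, of 11 genes in the hormone-sensing-like clusters 7 (Ctrl), 11 and 12 (cKO), chosen after the values were seen. Prlr lay between 959.9 and 1357 CPM and Esr1 between 37.2 and 45.7 CPM in all 3, while Aldh1a3 stood at 609 CPM in cluster 11 and 13.6 and 29.2 CPM in clusters 7 and 12.

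In luminal-progenitor-like cells, genes of milk and secretion were lower in cKO, and for some of them a few cells held most UMIs. Of 13 measured, 8 were at least 1.5-fold lower and 2 higher, with a median log2 ratio of -0.89 at percentile 0, and of 14 luminal progenitor markers 8 were lower and 1 higher, with a median of -0.68. The 165 UMIs of the casein gene Csn2 in Ctrl lay in 3 of 689 cells, so its counting interval does not cover its error and no fold is given. The 3 highest Ctrl cells of each gene also held 92 of 156 UMIs of Csn1s1 and 163 of 241 of Lalba, the lactose synthesis gene. Without the 3 highest cells of each milk gene in each library, chosen after the data were seen, 5 of 11 milk genes were lower, with a median of -0.55 at percentile 0.26. The iron carrier gene Trf, a leading gene of the cluster itself, stood at 2379.5 and 792 CPM. Glycam1, a mucin-like gene, ran the other way, at 29.8 and 162 CPM, while it stood at 150278 CPM in cluster 8 of cKO. Basal markers had a median of -1.62, with 7 of 10 lower, but of -0.07, with 2 higher and 2 lower, when doublets were kept, so no direction is given for them.

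Inflammatory genes of luminal-progenitor-like cells were higher in cKO for 6 of 15 and lower for 3, with a median log2 ratio of 0.52. Myeloid markers were higher in these cells too, for 3 of 5, with a median of 1.04. Cxcl2, a neutrophil chemokine gene, stood at 672 CPM in Ctrl and 1954 CPM in cKO, and Il1b, the interleukin-1 beta gene, at 0.430 and 6.04 CPM, with UMIs in 0.581% and 1.36% of cells, while haptoglobin, Hp, stood at 137 and 16.5 CPM. Cyclins, their kinases and inhibitors had a median of 0.09, at percentile 95.1 of random lists, with 1 of 12 higher, Ccnd1 itself, and 3 lower. S phase genes had a median of 0.18 with 2 of 17 higher and 1 lower. This median lay at percentile 99.8 of random lists, whose median was -0.19. Cells with a UMI of Mki67 or Top2a, which mark dividing cells, were 0 of 689 in Ctrl and 1 of 1027 in cKO after thinning, against 0 of 1075 and 1 of 981 basal-like cells. In all luminal-like cells 3 of 17 mitotic genes were higher and 2 lower, with a median of -0.21, and 0.2496% and 0.0840% of thinned cells held a UMI of Mki67 or Top2a. Cluster 10, with the highest score for proliferation markers and Lyve1 among its leading genes, is outside the luminal-like cells and held 0.881% of kept cells in Ctrl and 3.20% in cKO. At resolution 1.0, proliferating-like cells formed a class of their own, with 16 cells in Ctrl and 52 in cKO. This class scored 0.46 for shared luminal and 0.4 for hormone-sensing markers, so dividing luminal cells may lie outside the luminal-like cells. The mitotic values above thus hold only for the cells left in each class.

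Among single genes of luminal-progenitor-like cells, the luminal keratin gene Krt18 was higher in cKO, at 19417 and 28123 CPM, while Krt8 stood at 6957 and 5679 CPM and Krt19 at 2062 and 1002 CPM. The highest ratios were those of Lhfpl4, with 3 and 126 UMIs and a ratio of 46.9 (15.7 to 231), Rpgrip1, 42.7-fold higher, Fam25c, 8.56-fold higher, and Sprr1a, a cornified envelope gene, 8.14-fold higher. The hormone gene Cck was 6.28-fold lower, and the secreted ribonuclease gene Rnase1 26.6-fold lower. Calca, with 0 UMIs in cKO, was at least 229.9-fold lower and Plac8 7.07-fold lower (4.82 to 10.7), and both stood far higher in the hormone-sensing-like cells of Ctrl, at 3633 and 1753 CPM.

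In basal-like cells of cKO, shared luminal genes stood at higher levels, and free RNA of luminal cells was not excluded as their source. Of 8 shared luminal markers 5 were at least 1.5-fold higher and 0 lower, with a median log2 ratio of 0.95, as for Krt18 at 498 CPM in Ctrl and 1041 CPM in cKO and the tight junction gene Cldn4 at 13.6 and 48.1 CPM, while Prlr, a marker of hormone-sensing cells, stood at 5.84 and 17.4 CPM. If all Prlr and Csn3 RNA in basal-like cells were free RNA, it would bring up to 57.4% of the Krt18 difference, 72.8% for Cldn4, 81.7% for Cldn3, 96.9% for Cldn7 and 118.8% for Krt7, which are the 5 higher markers, 154.3% for Krt19 and 12.6% for Epcam. Of 12 basal markers 5 were higher and 2 lower, with a median of 0.45, the latter being Apoe, at 4124 and 1642 CPM, and Trp63, which encodes the basal transcription factor p63, at 69.6 and 32.7 CPM. Fn1, the fibronectin gene, stood at 1.74 and 17.0 CPM, with UMIs in 1.02% and 1.93% of cells, and the matrix protein gene Mgp at 363 and 47.8 CPM. Heat shock and immediate early genes had a median of -0.32 at percentile 0, although only 3 of 19 were at least 1.5-fold lower and 2 higher, with Hspa1a at 779 and 170.0 CPM. Genes of antigen presentation had a median of -0.31, with 4 of 11 lower and 0 higher. Myeloid markers were lower as well, for 3 of 4 measured, with a median of -0.99.

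Cytokine genes of basal-like cells were higher for 6 of 13 and lower for 2, with a median log2 ratio of 0.08. Ccl2, a monocyte chemokine gene, stood at 112 and 322 CPM and the NF-kB inhibitor gene Nfkbia at 428 and 1209 CPM. Among single genes, Rpgrip1 had 0 UMIs in Ctrl and was at least 126.9-fold higher in cKO, and the noncoding Gt(ROSA)26Sor was 14.1-fold higher. Npw, a neuropeptide gene, was 29.3-fold lower and Serpina3n, a protease inhibitor gene, 6.47-fold lower. Estrogen receptor targets had a median of 0.18, with 4 of 16 higher and 3 lower.

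**Figure D4:**
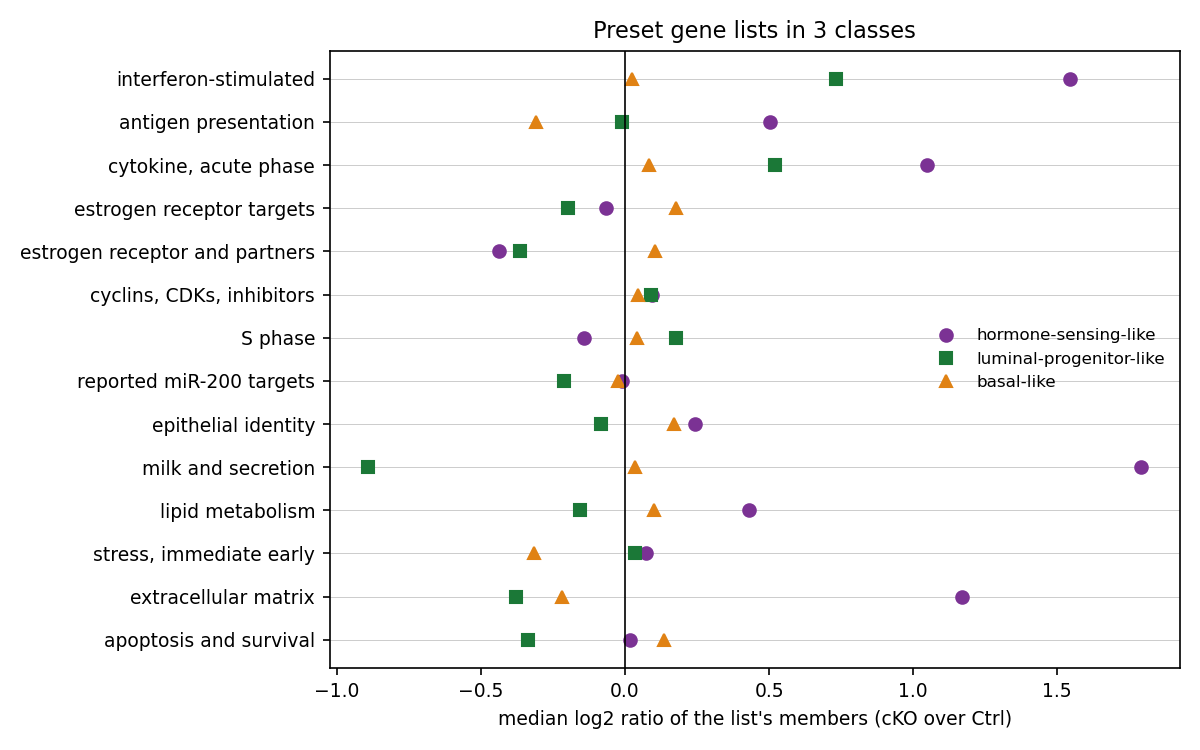
Points show the median log2 ratio, cKO over Ctrl, of 14 preset gene lists in hormone-sensing-like, luminal-progenitor-like and basal-like cells. Interferon-stimulated genes stood at 1.54, 0.73 and 0.02 and milk and secretory genes at 1.79, -0.89 and 0.03, and without cluster 11 the hormone-sensing-like values were 1.12 and 0.20.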

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

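Of the tests in this part, the spread of the hormone-sensing part of the UMIs was planned before its result was seen, and all others were chosen after. In each of the following the 2 libraries stood opposite ways in 2 classes, and the difference was not tested. Basal markers had a median log2 ratio of 1.91 in hormone-sensing-like and -1.62 in luminal-progenitor-like cells, which was -0.07 with doublets kept. Luminal progenitor markers stood at 1.80 and -0.68, and milk and secretory genes at 1.79 and -0.89, in the same classes. The hormone-sensing-like values of the 3 lists were 0.43, -0.29 and 0.20 without cluster 11. Clustered without library-specific genes at resolution 1.0 they were -1.38, -0.59 and 0.48. Set against the main luminal-progenitor-like values above, milk and secretory genes kept opposite signs in both alternatives. Without cluster 11, however, 2 of 6 were higher and 1 lower, at percentile 88.3 of random lists. These 6 measured genes also stand against 13 in luminal-progenitor-like cells, so the medians do not cover the same genes. Basal markers kept opposite signs in the first alternative only and luminal progenitor markers in neither. Myeloid markers stood at 2.19 in hormone-sensing-like cells, or 0.58 with 2 of 5 higher without cluster 11, and at -0.99 in basal-like cells. Cbr2 stood at 6.89 in hormone-sensing-like cells, where it is among the leading genes of cluster 11 and was 3.21 without it, and at -2.34 in luminal-progenitor-like cells.

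Cluster 4 (910 cells of Ctrl) and cluster 5 (1291 cells of cKO) carried the markers of both luminal kinds. Random pairs of cells in 1 droplet are argued against, because cells with basal and luminal markers reached 2.17% and 7.61% of the number that random pairing implies. A hormone-sensing-like and a luminal-progenitor-like cell that stayed together could account for the clusters, since the interquartile range of the hormone-sensing part of the UMIs was 0.843 and 0.993 times that of synthetic pairs. It cannot be told apart from 1 cell in a state between both kinds, because the median UMIs were at least 2.11 times those of the higher kind and 0 of 2598 and 2491 genes stood 2-fold above both kinds, which a large mixed cell would also show. No effect of the genotype on these clusters was tested.

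In 4 classes measured, 6 of 7208 genes were at least 2-fold higher in cKO throughout, namely Fxyd2, Gm8797, Gt(ROSA)26Sor, Lhfpl4, Rpgrip1 and Rtp4. Another 5 were higher in Ctrl, namely Calca, Gpx3, Hspa1a, Neat1 and Plac8, whose causes were not tested. For Calca, Gpx3 and Plac8 the highest of the 4 classes in Ctrl stood 179-fold, 164-fold and 141-fold above the lowest. Free RNA is not excluded for these genes. Free RNA of other classes could bring 97.3% of the Fxyd2 level in basal-like cells of cKO. It could bring at most 7.64% for the other genes higher in cKO, in a test that replaced a first one left undecided by Rtp4. No effect of the deletion was tested, since the genes were chosen for a difference in all 4 classes. An allele or background that differs near the genes is left open, because Gt(ROSA)26Sor and Lhfpl4, 100662 bases apart on chromosome 6, were seen to lie close before the draws were made, of which 0.34% of 10000 held a pair as close. These are 2 of 16 measured genes within 1000000 bases, while Gm8797, Rpgrip1 and Rtp4 lie on chromosomes 3, 14 and 16, Mir200c lies 11650894 bases from Gt(ROSA)26Sor and the insertion site of the Cre is not given in the sources used here.

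Ccnd1 was higher in luminal-progenitor-like cells of cKO. RNA of other cells is argued against, because the class that brings most accounts for 3.35% of the difference, and so is scaling, with a lowest log2 ratio of 0.93 over 3 scalings. Depth as the whole cause is argued against by cells thinned to equal depth, where the lower bound of the cKO share exceeded the upper bound of the Ctrl share by a log2 ratio of at least 0.14 at 1000 and 2000 UMIs. Whether loss of repression acts alike in both luminal kinds cannot be decided here. In hormone-sensing-like cells the upper bound of the CPM log2 ratio was 0.21, but it covers counting error only. These cells also lay almost wholly in different clusters in Ctrl and cKO. Single draws of 1000 UMIs gave shares higher in cKO in hormone-sensing-like cells and in basal-like cells (log2 ratio 0.78). The average over all draws gave log2 ratios of 0.79 (95% bootstrap interval over cells 0.60 to 0.99) in luminal-progenitor-like, 0.14 (-0.05 to 0.33) in hormone-sensing-like and -0.05 (-0.41 to 0.30) in basal-like cells. An effect of the deletion in luminal progenitor cells and a difference between the mice, sorts or preparations stay open, since 1 library per group cannot part them, and Ccnd1 was also higher in both-marker cells and cluster 8 of cKO, at log2 ratios of 0.67 and 0.29.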

How the results depend on the processing

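Clustering without library-specific genes, leaving out cluster 11, other counts of the clusters with both marker sets and equal weights were chosen after the data were seen. No paired analysis was possible because each group is 1 library. Of the alternatives for the 12 planned results 106 kept the value within its counting interval, 30 moved it and 4 reversed it, and for single genes these were 684, 79 and 6. A change of sign counts as a reversal only where the value lay outside its counting error of 0, so the Esr1 share and the mitotic genes, which also changed sign below, count as moved. Named genes kept their sign in 756 of 769 alternatives. Esr1 in hormone-sensing-like cells lay between -0.12 and 0.07, Ccnd1 between 0.90 and 1.07 in luminal-progenitor-like and -0.07 and -0.01 in basal-like cells. For the values below the cause was not tested, unless said.

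The hormone-sensing share differed by 14.2 points, by 8.52 with the looser cell filter, 6.86 without cluster 11, 5.99 with each cell with both marker sets counted as 1 of each kind, and 52.1 without library-specific genes at resolution 0.5, which named only 17 Ctrl cells, too few to give most hormone-sensing values. The basal share differed by -18.2 points, by -29.4 in that clustering and -12.8 with both marker sets counted in. The Esr1 share differed by 0.820 points, by 2.01 in that clustering and by -1.16 not thinned, where depth differs by construction. Ccnd1 in hormone-sensing-like cells turned to -0.0819 with the looser filter, -0.0248 without library-specific genes at resolution 1.0 and -0.0219 without cluster 11, and in luminal-progenitor-like cells was 1.07 with trimmed means. Estrogen receptor targets stood at -0.41 with the looser filter, -0.32 with libraries clustered alone, -0.29 without library-specific genes at resolution 1.0, -0.29 with at least 100 UMIs and -0.36 without cluster 11. Reported miR-200 targets stood at -0.0391 with trimmed means and -0.0162 with means of cells. Mitotic genes stood at 0.33 without library-specific genes and -0.49 with both marker sets counted in.

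Genes with a miR-200c site stood at -0.12 without library-specific genes, -0.0718 with 8-base sites, -0.000614 with lists matched on length, -0.0199 in basal-like cells, -0.0210 with both marker sets counted in and -0.0102 with equal weights. For miR-141 these were -0.11, -0.0636, 0.00502, -0.0199, -0.0255 and -0.00956, and -0.0184 without cluster 11. Pgr in hormone-sensing-like cells turned to 0.0758 with the looser filter, 0.0319 with means of cells and 0.0335 without cluster 11, Krt8 there to 0.0267 with trimmed means, Krt18 there to -0.0143 with means of cells, and Krt5 in luminal-progenitor-like cells to 0.41 with doublets kept. Trimmed means shifted all genes of hormone-sensing-like cells by 0.0527, and the Krt8 change is that shift. Depth limits Zeb1, Zeb2 and the mitotic genes, which had few UMIs.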

Other observations

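The genes and clusters in this part were chosen after their values were seen, and the permuted sites were added then too. Cluster 11 of cKO held UMIs of hormone-sensing genes and of Foxj1 and Dynlrb2. In it 97.1% of cells held a Prlr UMI, 58.3% an Esr1 UMI, 38.6% a Foxj1 UMI, 51.7% a Dynlrb2 UMI and 75.7% an Il33 UMI, at a median of 17665.5 UMIs per cell and without thinning. In cluster 7 of Ctrl Foxj1 was seen in 0.391% and Il33 in 1.37% of cells, at a median of 20489.5 UMIs, and in cluster 12 of cKO in 3.26% and 13.1%, at 11963 UMIs. Greb1 stood at 78.7 CPM in cluster 11, 47.4 in cluster 12 and 16.3 in cluster 7, and Cited1 at 385, 870 and 2397 CPM.

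Interferon-stimulated genes were also higher outside the classes of the report. In luminal cells with both marker sets 13 of 17 were at least 1.5-fold higher in cKO and 0 lower, with a median log2 ratio of 1.15. Markers of other cell types were higher there too, with medians of 2.04 for endothelial, 1.82 for T and NK cell and 1.38 for myeloid markers. In cluster 8, which carries endothelial and myeloid markers, 15 of 18 were higher, with a median of 1.90, and 12 of 16 in the endothelial-like cluster 9, with a median of 1.27. Of 20 mitotic genes 18 were higher in cluster 8, with a median of 1.83. Clusters 8 and 9 held 55 Ctrl cells each, under the minimum of 100 cells, and the FACS gate bears on which of these cells were kept.

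Permuted 7-base sites gave another scale for the genes with seed sites. Among 420 permutations of the miR-200c site, the difference for miR-200c lay at percentile 41.3 in luminal-like, 67.0 in hormone-sensing-like, 12.4 in luminal-progenitor-like and 75.1 in basal-like cells. For miR-141 the percentiles among these same permutations were 55.5, 55.0, 32.9 and 73.8. The miR-141 site has another base composition than the permuted miR-200c site, so they are not a matched scale for it.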
